A study of Mus musculus with 8 samples.

How the data were processed

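Per the labels, nucleus accumbens tissue of D1R:Cre mice was dissociated with papain and sorted by fluorescence into 4 fractions per experiment, RNA was purified with a Qiagen RNeasy kit, libraries were made with SMART-seq v4 and sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes, reads were aligned to GRCm38 with STAR and counted per gene with HTSeq; the versions of both are not given in the sources used here. The deposited counts, of 49585 genes by 28 libraries, was used as raw counts. The deposited per-sample tables hold 24 of these libraries, without experiment sh4, with identical counts, and were used only as an alternative. Reads were not realigned here. Of the gene names, 47333 matched GENCODE M21 (GRCm38), from which coordinates were taken, and 93 repeated names were kept as separate genes.

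Groups were formed from virus (scrambled or shShank3), D1 class and infection gate, giving 8 groups of 3 scrambled or 4 shShank3 libraries, 28 in all, with each library used once. A library is 1 sorted fraction of 1 experiment. The labels state that the 4 fractions come from the same experiment, so fractions are paired within experiments, whereas the labels do not tie experiment numbers across the viruses. Libraries of sh1 were run on lane 3 and the others on lane 7. Counts were normalised by TMM (factors 0.807 to 1.314) after filterByExpr by group, which kept 18744 genes. A quasi-likelihood negative binomial model with 1 coefficient per group was fitted with edgeR 4.0.16 (robust, 20 residual degrees of freedom) in R 4.3.3, and the common dispersion was 0.486 (biological coefficient of variation 0.697). Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its comparison. Log2 CPM values were computed with a prior count of 2. The standard error is the log2 fold change divided by the root of the F statistic. Where a whole group had 0 counts, the fold is given as at least the ratio to a floor of 3 counts over the group, which covers counting error only.

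There were 11 comparisons: shShank3 against scrambled in infected cells (mean of D1 classes, D1pos, D1neg, and D1pos minus D1neg) and in uninfected cells (mean, D1pos, D1neg). The others were the difference of infected and uninfected cells in the virus effect (interaction), D1pos against D1neg cells over all viruses and gates, and infected against uninfected cells with the scrambled and with the shShank3 virus. Comparisons, groups, filter and a first set of alternatives were chosen before the data were examined. Genes named in the text were picked by rule: Shank3, Trpv4, Drd1 and Drd2 always, and the 10 called genes per direction with the largest log2 fold change, a mean log2 CPM of at least 3 and no overlap between the sides within either D1 class. Where nothing was called, 8 per direction with at least 20 CPM in the higher group were named. From each gene list described, up to 4 members with the largest absolute log2 fold change were also named. Genes named outside these rules are said to be so in the text.

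Gene lists were written before the counts were seen, and 27 were used: D1 MSN, D2 MSN, pan-MSN, striatal interneuron, glutamatergic projection neuron, astrocyte, microglia, infiltrating immune cell, oligodendrocyte, oligodendrocyte precursor (OPC), endothelial and mural, and ependymal and choroid markers. Others were immediate early, heat shock, interferon response, antigen presentation, p53 target, and unfolded protein and integrated stress response genes, postsynaptic density scaffold, glutamate receptor, GABA-A receptor and inhibitory synapse, TRP channel, potassium channel, and sodium, calcium and HCN channel genes, and ribosomal protein, mitochondrially encoded and nuclear oxidative phosphorylation genes. For each list the members called over all genes, those called when adjusted over the list alone, the median log2 fold change, and camera (limma 3.58.1) with a preset correlation of 0.01 and with the correlation estimated from residuals are given, with fry as an alternative. List p-values were adjusted over the 27 lists of a comparison. Those of the cell cycle list, chosen later, were adjusted over it and a neuroblast list only. Marker levels are means of log2 CPM over list members. Of the 9 infiltrating immune genes 6 were measured, namely Mrc1, Cd163, Lyz2, Ms4a7, Cd79a and S100a8. The listed Cd3e, Cd8a and Nkg7 were not among the tested genes. A rise of this list can thus come from macrophage genes and does not show infiltration. Of the 5 ependymal and choroid genes 4 were measured, namely Foxj1, Ccdc153, Tmem212 and Dynlrb2. The listed choroid gene Ttr was not among the tested genes, so the level of that list does not bear on choroid plexus.

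Alternatives were RLE, upper-quartile and raw-total scaling, DESeq2 1.42.0, limma-voom, no filter and a strict filter (CPM of at least 5 in at least 2 libraries). Further ones were the per-sample tables, counts summed over the libraries of a group (8 summed samples, additive model, with and without a D1 class by virus term), only the groups compared, a block for experiment number, and leaving out each library. Alternatives chosen after seeing the data were leaving out each whole experiment, a block for the experiment where fractions of an experiment are compared, limma-voom with the correlation of fractions of an experiment estimated (0.257), and summing the D1 fractions of an experiment and gate. The tests were run on simulated counts, with 200 of the 18744 genes changed 2-, 4- or 8-fold. These counts were drawn for each library on its own, without correlation among fractions of an experiment or differences in cell content. The unchanged genes called therefore do not measure false calls that such features of the real data could give. For the mean of infected cells edgeR recovered 6, 53.7 and 66.7% of them with 5 unchanged genes called, and for D1pos infected cells 4.5, 26.9 and 51.5% with 2. It recovered for the interaction 0, 38.8 and 48.5% with 2, for infection with shShank3 9, 53.7 and 68.2% with 4, and for the D1 comparison 28.4, 53.7 and 75.8% with 2. DESeq2 called 37 to 53 unchanged genes. The virus comparisons were also rerun with whole experiments regrouped in every other way, keeping group sizes, and the ways within equal experiment numbers were counted after the results were seen. For the D1 and infection comparisons the labels of the compared fractions were swapped within pairs, in all or a sample of the ways, with each pair of an experiment swapped on its own, and then, as a test added after the results were seen, with all fractions of an experiment swapped together in every way. Other software was the package data.table (version 1.17.8) and, for a published cell cycle gene list only, Seurat 5.3.0. A gene picked by the rule is not reported here. Transcript isoforms, reads on the viral vectors and sequence variants were not analysed here.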

Results

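RNA was measured in cells of the mouse nucleus accumbens, a ventral striatal nucleus whose principal cells are medium spiny neurons (MSNs) carrying either the D1 or the D2 dopamine receptor. D1R:Cre mice on a C57Bl/6j background, aged postnatal day 28 to 32, had received an adeno-associated virus with either a scrambled hairpin or a hairpin against Shank3, which encodes a scaffold protein of the postsynaptic density. Cells were dissociated with papain and sorted into 4 fractions per experiment, by D1 receptor expression (D1pos or D1neg) and by viral fluorescence (infected or uninfected). There were 3 scrambled experiments (scr1 to scr3) and 4 shShank3 experiments (sh1 to sh4), giving 28 libraries in 8 groups of 3 (scrambled) or 4 (shShank3) libraries. The viruses also differed in serotype (AAV1 or AAV5) and in fluorophore, so that a difference between them is not one of the hairpin alone. Libraries held 9.03 to 31.7 M counts (median 18.26), with a median of 21.8 M for the scrambled and 17.08 M for the shShank3 libraries. Between 17015 and 21500 genes were detected per library. The labels do not say that experiments were separate animals, so p-values measure only the spread between these samples. No 2 libraries of a group were alike within sampling noise (chi-square per gene 53.3 to 668). Values are means ± SD over libraries in CPM (counts scaled by normalised library size), fold changes are log2 ± SE, and p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

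The knockdown target was examined first. Shank3 (chromosome 15, 89499623 to 89560261, plus strand, GRCm38) was at low levels in every library. In the shShank3 infected fractions it was at 2.27, 3.01, 11.1 and 2.18 CPM in D1pos cells and 2.14, 2.65, 25.96 and 5.59 CPM in D1neg cells of sh1 to sh4. The uninfected partners held 2.94, 3.39, 13.6 and 13.4 CPM (D1pos) and 4.33, 8.37, 47.8 and 17.6 CPM (D1neg), so that Shank3 was lower in the infected library in 8 of 8 pairs. In the scrambled experiments the infected libraries held 4.57, 3.95 and 7.14 CPM (D1pos) and 9.97, 13.7 and 9.09 CPM (D1neg), against 3.06, 8.12 and 15.7 CPM and 8.77, 10.2 and 13.1 CPM uninfected, lower in 3 of 6 pairs. The infected-to-uninfected difference was -0.98 ± 0.56 with shShank3 (adjusted p = 0.915) and -0.37 ± 0.64 with the scrambled hairpin (adjusted p = 0.934), and the difference between these differences was -0.61 ± 0.84 (adjusted p = 0.952). With the experiment as a block the shShank3 difference was -1.06 (adjusted p = 0.231, the lowest over all alternatives, which ran up to 1). Between viruses, infected fractions differed by -0.23 ± 0.59 (adjusted p = 0.872). None of these Shank3 differences passed the test. Shank3 in the infected libraries labelled sh3 lay above the scrambled infected libraries of the same D1 class, and without sh3 the difference between viruses was -1.34 (adjusted p = 0.0525, the lowest over 35 alternatives, which ran up to 1). The sh3 D1neg libraries also had the highest mitochondrial shares of the 28 (10.48% uninfected, 13.35% infected), with 30.1% and 34.9% of counts in their 10 most abundant genes. Their pan-MSN marker levels were the highest of the 28 as well (8.28 log2 CPM uninfected, 8.26 infected). More neuron RNA is thus not separated from the high Shank3 in them.

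Trpv4 (chromosome 5, 114622152 to 114658421, minus strand), the calcium-permeable TRP channel named in the study's title, rose in the shShank3 infected fractions. It was at 8.86 ± 1.18 CPM in D1pos and 9.73 ± 7.87 CPM in D1neg infected cells with shShank3 (n = 4 each). With the scrambled hairpin it was at 0.984 ± 0.591 and 1.05 ± 0.937 CPM (n = 3 each), a difference of 3.19 ± 0.79 (9.14-fold, adjusted p = 0.0202). The sh3 D1neg infected library, at 1.37 CPM (11 counts), lay within the scrambled D1neg infected range of 0 to 1.80 CPM. Its uninfected partner held 0.399 CPM (4 counts), so that pair compares few counts. Uninfected cells held 1.99 ± 1.36 (D1pos) and 3.57 ± 3.05 CPM (D1neg) in the shShank3 and 1.96 ± 2.12 and 8.30 ± 3.13 CPM in the scrambled experiments, a difference of -0.59 ± 0.69 (adjusted p = 0.937). Trpv4 was higher in the infected than in the uninfected library in 8 of 8 shShank3 pairs (1.80 ± 0.66, adjusted p = 0.593) and lower in 5 of 6 scrambled pairs (-1.99 ± 0.77, adjusted p = 0.284). The difference between those differences was 3.78 ± 1.02 and did not pass the test (adjusted p = 0.125, with 0.00425 to 0.463 over 49 alternatives; 0.0803 with the experiment as a block). The call between infected fractions was lost without the scr2 D1pos infected (adjusted p = 0.0577) or the scr3 D1pos infected library (0.0588), and without all of experiment scr2 (0.102), scr3 (0.102), sh1 (0.0779) or sh4 (0.063). It was also lost with the D1 fractions of an experiment and gate summed, where these fractions no longer count as separate. Microglial, border macrophage and endothelial markers were also higher in the shShank3 than in the scrambled infected fractions, as described for the infected fractions.

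**Figure D1:**
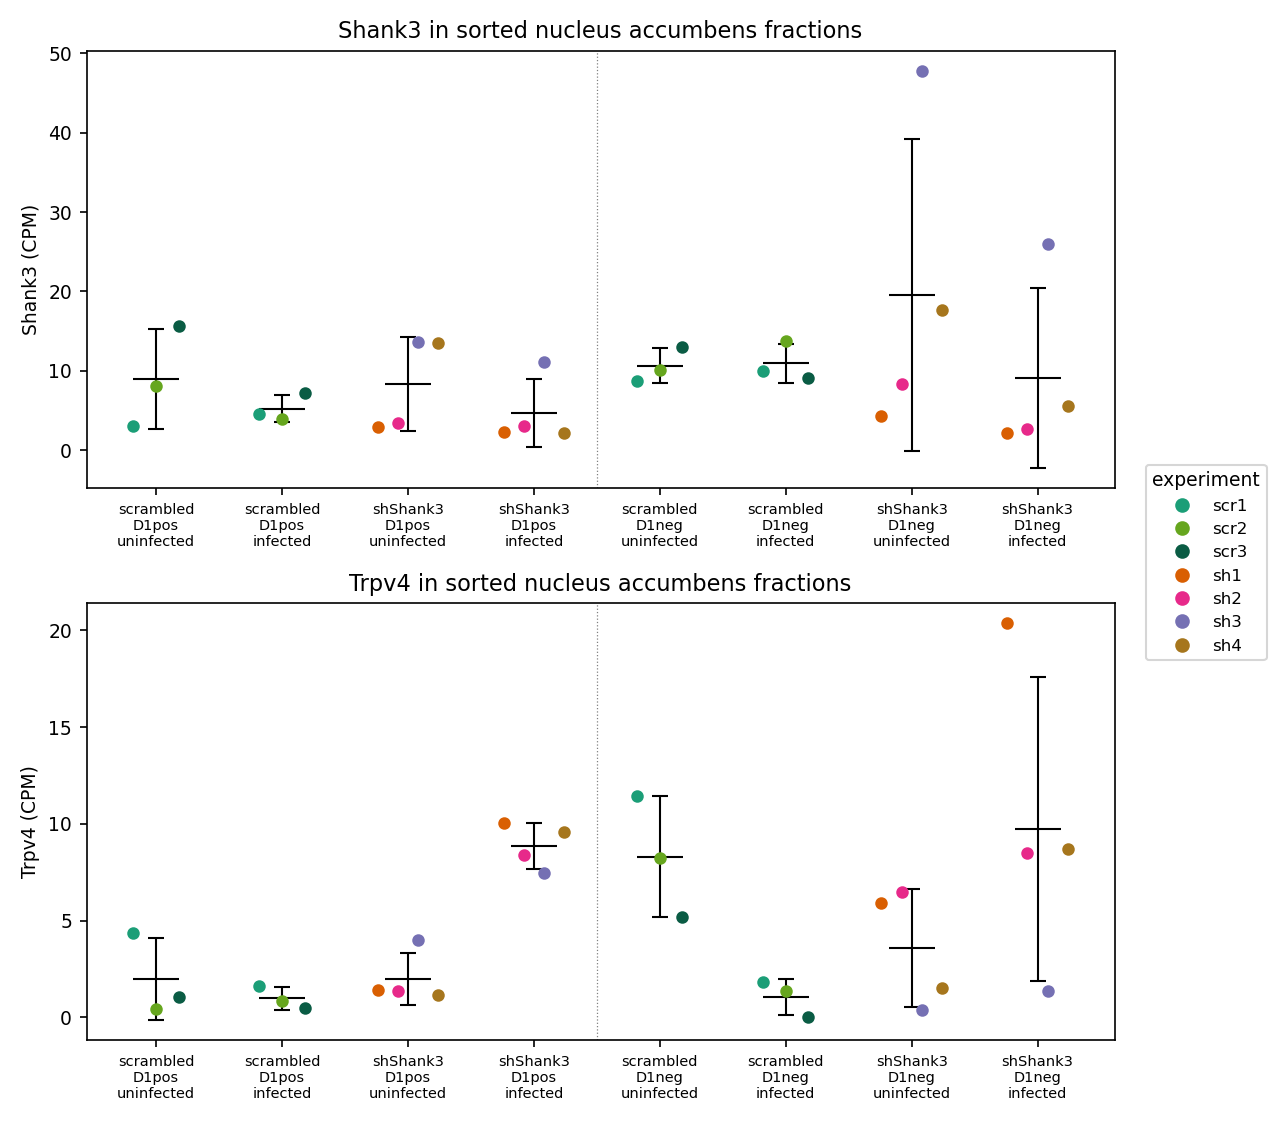
Shank3 and Trpv4 levels (CPM) per library in the 8 groups, with each point a library coloured by experiment, the horizontal bar the group mean and the error bars the SD. Trpv4 lay at 8.86 and 9.73 CPM on average in the shShank3 infected groups and at 0.984 and 1.05 CPM in the scrambled infected groups, while Shank3 in the sh3 libraries stood above the other shShank3 libraries in all 4 fractions.

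The D1 sort was compared next, as D1pos against D1neg cells over both viruses and gates. Astrocyte genes were the leading genes higher in D1pos cells, where all 10 astrocyte markers rose (10 adjusted over the list alone; median 2.93). Gja1, the connexin gene of astrocyte gap junctions, rose by 3.32 ± 0.33 (adjusted p = 9.13e-08). It was at 4720 and 6293 CPM in scrambled and shShank3 D1pos infected cells against 1350 and 531 CPM in D1neg ones. Also higher were Fgfr3 (3.22 ± 0.33) and Aldoc (2.98 ± 0.28). Microglia markers went the other way, with 11 of 11 lower in D1pos cells (median -4.58), as for Tmem119 (-5.44 ± 0.77) and Cx3cr1 (-5.38 ± 0.74). Of 9 endothelial and mural markers 8 fell, as for Acta2, the smooth muscle actin (-6.15 ± 0.72). Drd2 was lower in D1pos cells (-2.20 ± 0.61, adjusted p = 0.00665; lower in 6 of 6 scrambled and 7 of 8 shShank3 pairs), and 4 of 7 D2 MSN markers fell (6 adjusted over the list alone; median -1.64). Drd1 was higher in D1pos cells in 5 of 6 scrambled pairs, with no difference to 2 decimals in the sixth, and in 6 of 8 shShank3 pairs, but its difference of 0.76 ± 0.55 did not pass the test (adjusted p = 0.305).

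**Figure D2:**
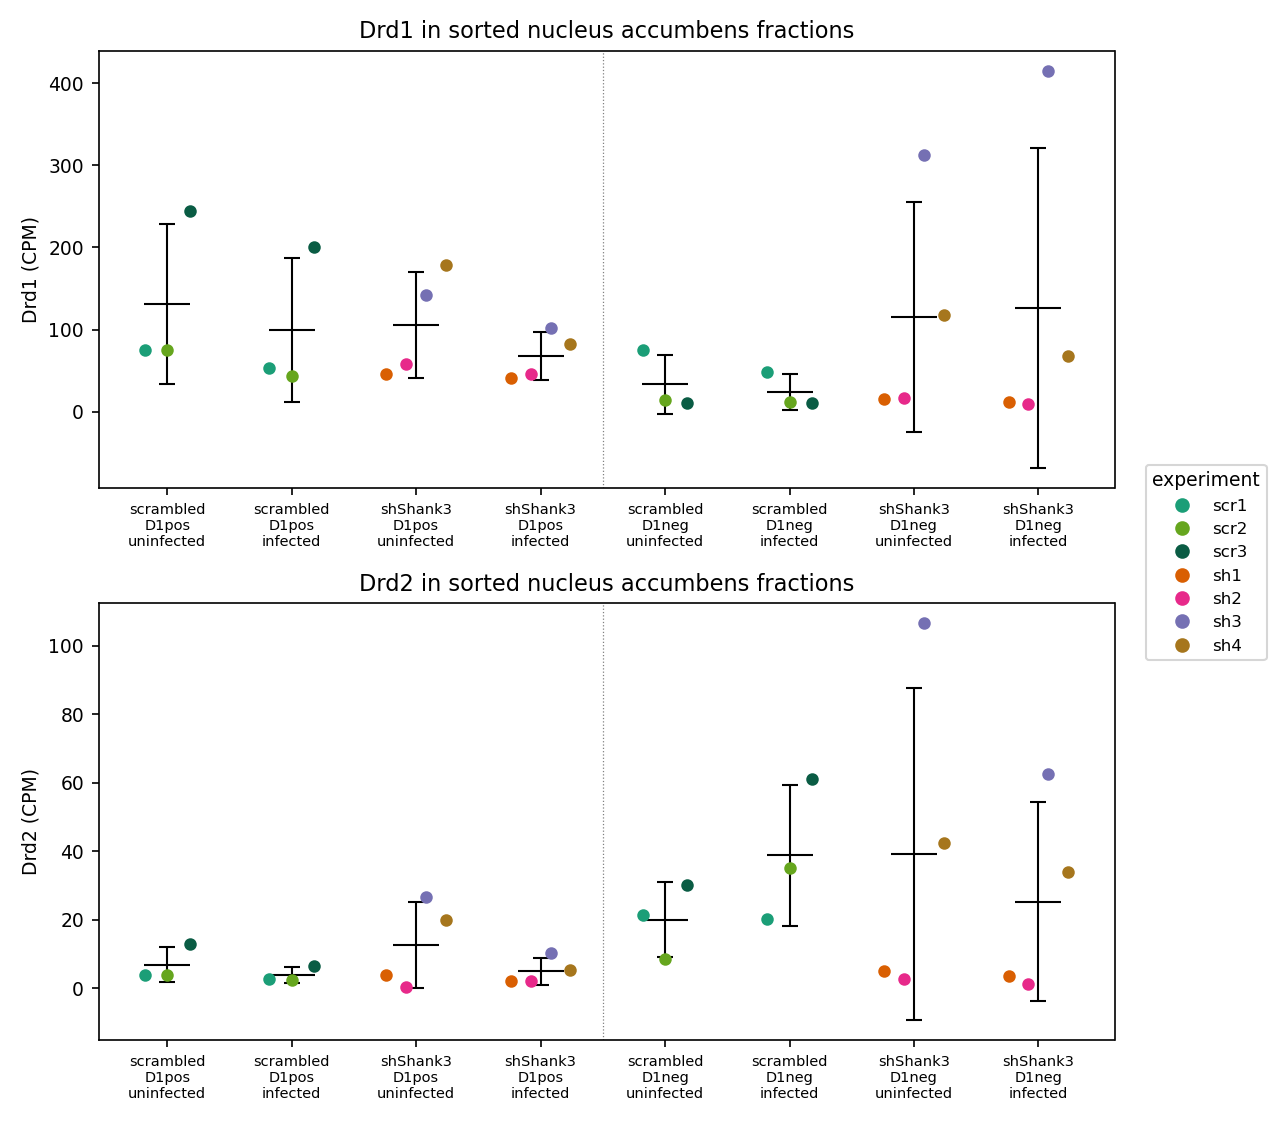
Drd1 and Drd2 levels (CPM) per library in the 8 groups, with points coloured by experiment, the horizontal bar the group mean and the error bars the SD. Drd2 was lower in the D1pos than in the D1neg groups (log2 difference -2.20), and in sh3 Drd1 was higher in the D1neg libraries (415 and 313 CPM) than in the D1pos libraries (102 and 142 CPM).

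In all, 3123 genes were higher and 3133 lower in D1pos cells. The balance depended on the scaling, with 2794 higher and 3637 lower under RLE and 2219 and 4540 (32.8% higher) with raw totals. The other named genes with the largest rises were Cyp4f14, Atp13a4, Cyp4f15, Slc7a10, Acsbg1, Fam198a, Hgf and AI464131 (3.18 to 3.45), and the other largest falls were Dcn (-5.49), Col3a1, Olfml3, Mylk, Tpm2, Gja4, Vtn, Edn3 and F11r (-4.21). Dcn and Col3a1 are extracellular matrix genes of fibroblasts, and Mylk and Tpm2 belong to the contractile apparatus of smooth muscle. Among D1 MSN markers Sfxn1 (1.39 ± 0.23) and Eya1 (1.24 ± 0.42) rose and Ebf1 fell (-3.45 ± 0.40), and among pan-MSN markers Foxp1 fell (-1.36 ± 0.37). Ependymal markers rose (4 of 4; median 2.34, or 2.01 with genes at 0 in a group set to their bound). Lower in D1pos cells were 7 of 12 immediate early genes (8 adjusted over the list alone), 8 of 10 antigen presentation genes and 7 of 12 interferon response genes. So were 74 of 81 ribosomal protein genes (77 adjusted over the list alone; median -0.67). Of 92 nuclear oxidative phosphorylation genes 27 rose and 3 fell. TRP channel genes went both ways (3 higher, 6 lower), with Trpc4 (-3.18 ± 0.67) and Trpv2 (-3.05 ± 0.46) among those that fell. Among genes of the synaptic and channel lists that astrocytes are known to express, Gabrg1 (2.99 ± 0.29), Grm3 (2.89 ± 0.25) and Kcnk1 (2.79 ± 0.30) rose. Heat shock genes (3 of 8; 4 adjusted over the list alone), OPC markers (2 of 6; 3 adjusted over the list alone), infiltrating immune markers (2 of 6) and interneuron markers (2 of 12) were called lower. Of 24 glutamate receptor genes 2 were higher and 3 lower (2 and 0 adjusted over the list alone), and 3 of 21 postsynaptic density scaffold genes rose. No camera call on these lists held with an estimated correlation. The adjusted p was 0.173 for astrocyte, 0.39 for microglia, 0.263 for endothelial and 0.51 for D2 MSN markers. It was 0.375 for immediate early genes, 0.442 for ependymal markers, 0.409 for antigen presentation and ribosomal protein genes and 0.716 for oxidative phosphorylation genes. With the experiment as a block, Drd1 (1.44, adjusted p = 0.0105) and Shank3 (-0.75, adjusted p = 0.0141) passed the test. Over all alternatives their adjusted p ran from 0.00349 to 1 and from 0.0141 to 0.313. The block also raised the pan-MSN markers called lower from 1 to 8, the D2 MSN markers from 4 to 7, the glutamate receptor genes from 3 to 12 and the sodium, calcium and HCN channel genes from 5 to 17. Drd1 also passed without the sh3 D1neg infected library (adjusted p = 0.0478), and Shank3 without the sh3 D1pos infected library (0.0422).

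Infected cells were then compared between the viruses, as the mean over D1 classes, which asks how cells with the Shank3 hairpin differ from cells with the scrambled hairpin. In the comparisons between viruses, rose and fell are relative to the scrambled cells of the same gate. Genes of macrophages and microglia were higher with shShank3. Mrc1, the mannose receptor of border-associated macrophages (chromosome 2, 14229392 to 14332057), went from 11.2 ± 10.1 and 2.44 ± 2.71 CPM in scrambled D1pos and D1neg cells to 178 ± 36.3 and 184 ± 162 CPM (5.11 ± 1.02, adjusted p = 0.00788), with 1.73 and 18.02 CPM (scrambled) and 1.70 and 29.2 CPM (shShank3) in uninfected cells. The scavenger receptor gene Stab1 (4.00 ± 0.72, adjusted p = 0.00367), the prostaglandin pathway genes Hpgd (3.88 ± 0.72), Hpgds (3.59 ± 0.82) and Tbxas1 (3.68 ± 0.71) rose with it. So did the leukocyte gene Cd84 and the phagosomal metal transporter gene Slc11a1 (3.36 each). Vascular genes were also higher than with the scrambled virus, namely the endothelial transcription factor gene Sox18 (3.60 ± 0.48, adjusted p = 0.000496), Robo4 (3.62 ± 0.88) and Cd34 (3.17 ± 0.59). For these the scrambled infected cells were low: Sox18 was at 0.572 and 12.2 CPM in scrambled infected D1pos and D1neg cells against 10.3 and 83.5 CPM uninfected, and with shShank3 at 11.2 and 92.4 against 22.3 and 73.4 CPM. Genes of the cell cycle fell: Top2a, the topoisomerase of dividing cells (chromosome 11, 98992943 to 99024189), went from 38.0 ± 12.3 and 190 ± 97.9 CPM to 9.42 ± 6.34 and 16.7 ± 9.19 CPM (-2.76 ± 0.43, adjusted p = 0.00102), with 16.5 and 113 CPM (scrambled) and 33.0 and 68.9 CPM (shShank3) in uninfected cells. Cdca3 (-2.96 ± 0.45), Dtl (-2.95 ± 0.47), Pbk, Kif11, 2810417H13Rik, Uhrf1, Kif22, Mfap2 and Ccnb1 (-2.46 ± 0.53) fell too. All but Mfap2, a microfibril gene, have known parts in DNA replication or mitosis.

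**Figure D3:**
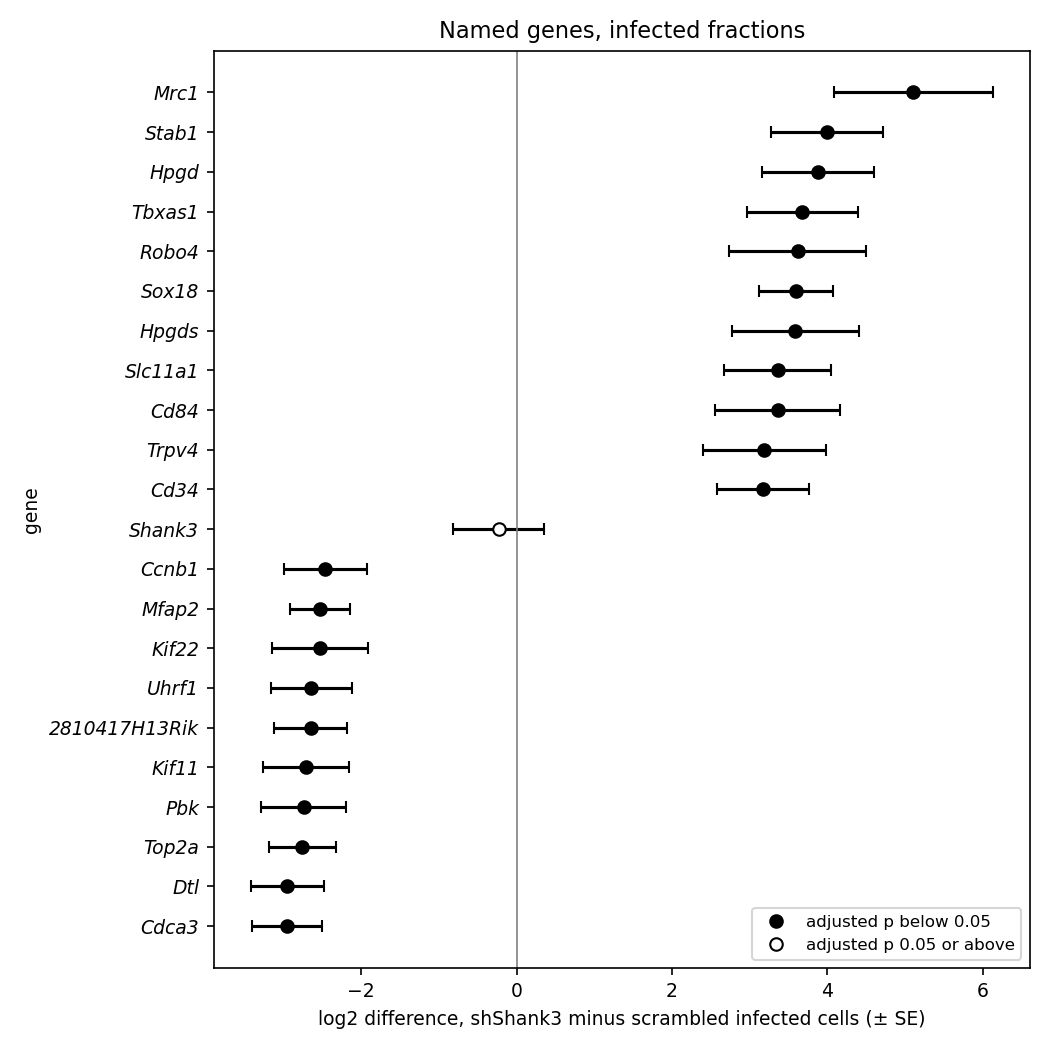
Log2 differences between shShank3 and scrambled infected cells for the named genes, as points with error bars of 1 SE, filled where the adjusted p was below 0.05. Macrophage and vascular genes lay above 0, up to 5.11 for Mrc1, and cell cycle genes below 0, down to -2.96 for Cdca3.

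In this comparison 829 genes rose and 619 fell, and 4693 had an unadjusted p below 0.05. All 11 microglia markers rose (11 adjusted over the list alone; median 3.58), as for C1qa (3.74 ± 0.85), C1qb (3.93 ± 0.90) and Csf1r (4.07 ± 1.00). Of 6 infiltrating immune markers 4 rose (5 adjusted over the list alone; median 4.03, or 3.97 with genes at 0 set to their bound), as for Lyz2 (4.54 ± 0.88) and Ms4a7 (4.63 ± 1.01). The microglia marker level was 5.97 ± 0.71 (D1pos) and 9.47 ± 2.94 (D1neg) log2 CPM in shShank3 infected cells against 3.15 ± 1.48 and 5.37 ± 1.59 in scrambled infected cells. In uninfected cells it was 4.29 and 9.02 with shShank3 and 3.15 and 9.11 with the scrambled virus, so that in D1neg cells the scrambled infected ones stood apart. Of 9 endothelial and mural markers 5 rose (5 adjusted over the list alone; median 2.38), as for Flt1 (2.74 ± 0.47) and Cldn5 (2.65 ± 0.48). Of 10 antigen presentation genes 4 rose (6 adjusted over the list alone; median 1.16), as for Cd74 (3.73 ± 0.93) and B2m (1.39 ± 0.39). Among OPC markers Gpr17 rose (1.96 ± 0.54; 1 of 6, and 3 adjusted over the list alone). Of 8 oligodendrocyte markers none passed (6 higher adjusted over the list alone; median 1.37). Ependymal markers fell (3 of 4, and 4 adjusted over the list alone; median -3.73), as for Tmem212 (-4.17 ± 1.15) and Ccdc153 (-3.76 ± 1.03). Of 10 astrocyte markers Gfap fell (-1.05 ± 0.33; 7 adjusted over the list alone; median -0.97). The camera calls on these 8 cell type and immune lists, with adjusted p of 6.37e-09 to 0.00902, were lost with an estimated correlation (adjusted p = 0.206 for infiltrating immune markers and 0.454 for the others).

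**Figure D4:**
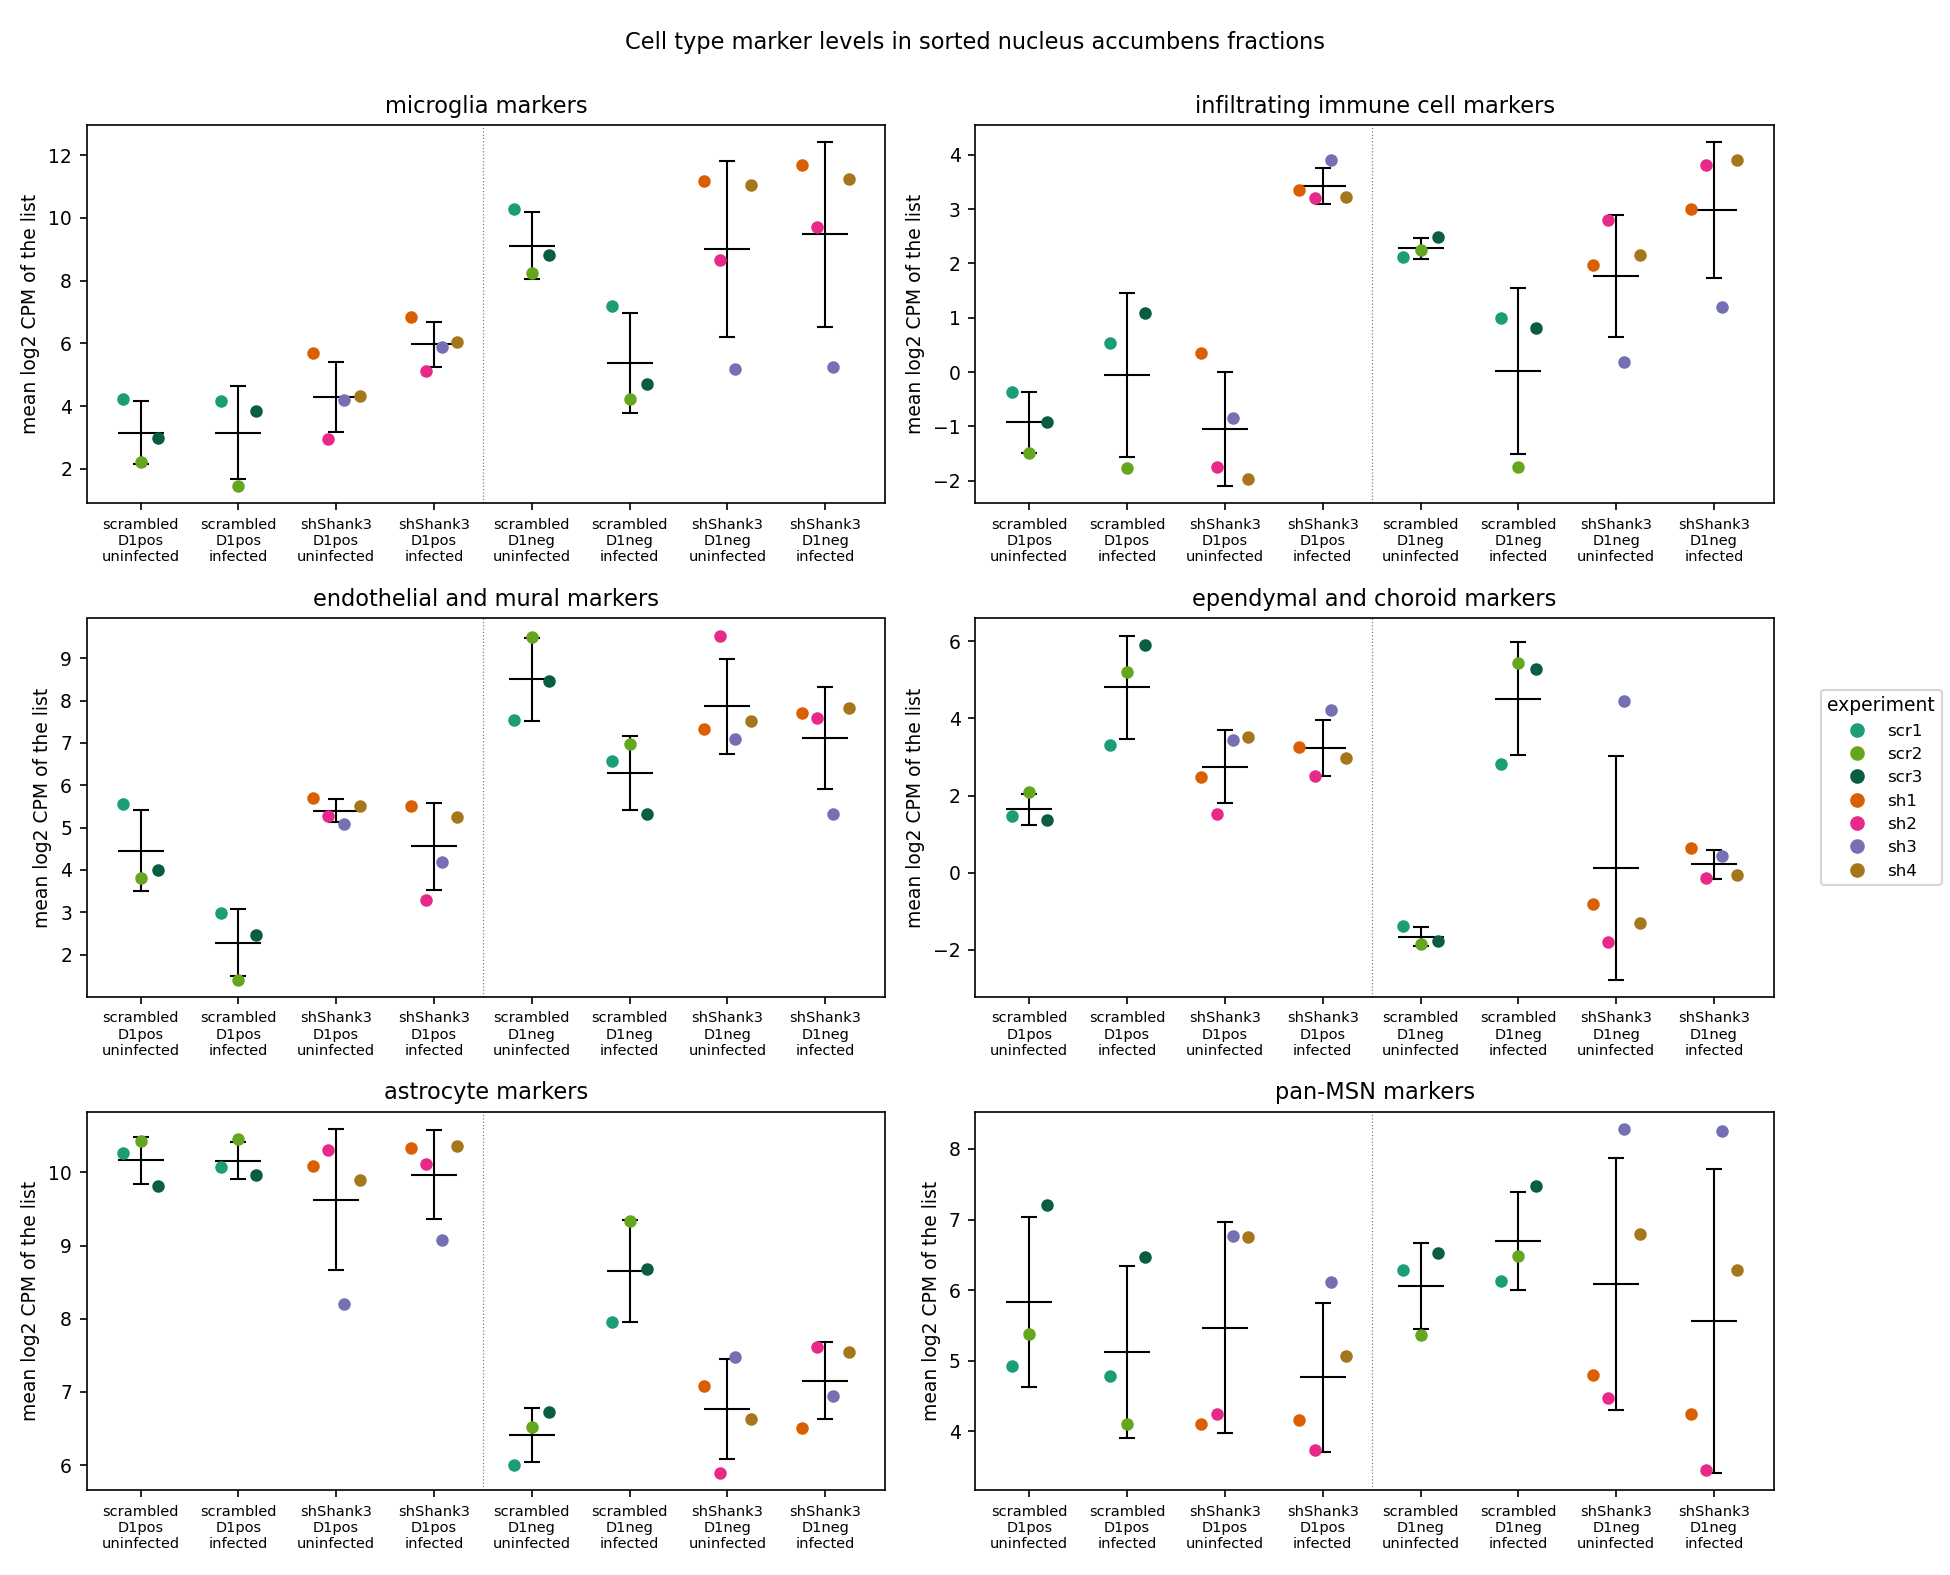
Mean marker levels (log2 CPM) of cell type lists per library in the 8 groups, with points coloured by experiment, the horizontal bar the group mean and the error bars the SD. Microglia markers lay at 5.97 and 9.47 in shShank3 infected D1pos and D1neg cells and at 3.15 and 5.37 in scrambled infected cells, while uninfected D1neg cells of both viruses lay near 9 (9.02 and 9.11).

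Few genes of the neuronal lists passed. None of 9 D1 MSN markers (median 0.49), 7 D2 MSN markers (-0.76), 12 pan-MSN markers (-0.36) or 7 glutamatergic projection neuron markers (1.52) passed, over all genes or adjusted over the list alone. The same held for 24 glutamate receptor genes (0.32), 29 potassium channel genes (0.22) and 25 sodium, calcium and HCN channel genes (0.52). On these last 3 lists camera pointed down against a positive median, with no call. Of 21 postsynaptic density scaffold genes only Dlg1, which encodes SAP97, rose (0.95 ± 0.26; 1 adjusted over the list alone; median 0.18). Of 21 TRP channel genes only Trpv4 did (1 adjusted over the list alone; median 0.41, or 0.36 with bounds). None of 16 GABA-A receptor and inhibitory synapse genes passed (0 adjusted over the list alone; median -0.29; camera adjusted p = 0.04, with adjusted p = 0.706 with an estimated correlation). Of 12 interneuron markers Calb2, the calretinin gene, fell (-2.65 ± 0.54; 1 adjusted over the list alone), with camera pointing down against a median of 0.28. None of 12 immediate early genes (0.18), 8 heat shock genes (0.39) or 8 mitochondrially encoded genes (0.79) passed, on either count. Rsad2 was the only interferon response gene of 12 to fall (-1.36 ± 0.40; 1 adjusted over the list alone; median -0.85). Of 10 p53 targets the cell cycle inhibitor gene Cdkn1a (-1.62 ± 0.26, adjusted p = 0.00136) and Sesn2 (-0.90 ± 0.23) fell (3 adjusted over the list alone). Of 10 unfolded protein and integrated stress response genes Sdf2l1 rose (1.38 ± 0.39; 2 higher and 1 lower adjusted over the list alone). Of 81 ribosomal protein genes Rpl10a (-0.75 ± 0.21) and Rps27l (-0.65 ± 0.20) fell (0 adjusted over the list alone; median -0.27). Of 92 nuclear oxidative phosphorylation genes 6 fell (6 adjusted over the list alone; median -0.33). Their camera calls on both lists (1.54e-06 and 1.39e-07) were lost with an estimated correlation (adjusted p = 0.706 and 0.454).

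Upper-quartile scaling moved the median of all genes by -0.12 in this comparison (-0.10 for D1pos and -0.15 for D1neg cells alone) and gave 672 higher and 903 lower genes (42.7% against 57.3% higher with TMM). Raw totals gave 552 and 1455 (27.5% higher). Removing 1 library moved the count by over 1.5 times for scr2 D1neg infected (569), scr2 D1pos infected (402), scr3 D1neg infected (375) and scr3 D1pos infected (504). It did so for sh1 D1neg infected (749), sh3 D1neg infected (2218), sh3 D1pos infected (873) and sh4 D1neg infected (884). Limma-voom with the correlation among fractions of an experiment gave 442 genes. Under it the microglia markers called went from 11 to 2, the infiltrating immune markers from 4 to 2, the antigen presentation genes from 4 to 1 and the endothelial markers from 5 to 0. The calls on Dlg1, Calb2, Rsad2 and Sdf2l1 were lost, as were those on Hpgd (adjusted p = 0.0955), Tbxas1 (0.106), Robo4 (0.0544), Hpgds (0.193), Cd84 (0.13), Slc11a1 (0.21), Kif11 (0.0649) and Kif22 (0.0688). Over all alternatives the adjusted p of Mrc1 ran from 1.03e-07 to 0.231, that of Sox18 from 2.28e-13 to 0.0722 and that of Top2a from 1.22e-08 to 0.0807. Of the named genes, Robo4 missed the threshold without scr2 D1neg, scr2 D1pos or scr3 D1pos infected (adjusted p = 0.0509, 0.0573 and 0.0535), and Hpgds without scr3 D1neg infected (0.0507). Cd84 missed it without scr2 D1pos or scr3 D1neg infected (0.0537 and 0.0572) and Kif22 without scr3 D1neg or scr3 D1pos infected (0.0628 and 0.0508). With whole experiments left out as well, the adjusted p reached 0.0627 for Hpgd, 0.0758 for Tbxas1, 0.0857 for Slc11a1 and 0.0672 for Cd34. It reached 0.0717 for Pbk, 0.0853 for Kif11, 0.0696 for Uhrf1 and 0.0845 for Ccnb1. Mrc1, Stab1, Sox18, Cdca3, Dtl, Top2a, 2810417H13Rik and Mfap2 stayed below 0.05. Over all alternatives each called named gene lay above 0.05 at least once, as for Stab1 (0.246) and Cdca3 (0.111).

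Within the D1 classes more genes passed in D1neg than in D1pos cells. In D1neg infected cells Mrc1 (6.23 ± 1.52, adjusted p = 0.028), Pde3b (5.22 ± 1.48), Hpgd (4.93 ± 1.07), Stab1 (4.70 ± 1.06), Hpgds, Arhgap27, Tbxas1, Slc11a1, Fam46c and Nrros (3.80 ± 0.86) rose. Rrm2, a subunit of the ribonucleotide reductase that makes deoxynucleotides, fell from 209.7 ± 116.1 to 9.81 ± 7.55 CPM (-4.40 ± 0.74, adjusted p = 0.0037). Cd24a, a surface protein of immature neurons, fell from 102.7 ± 51.8 to 7.53 ± 3.47 CPM (-3.76 ± 0.58, adjusted p = 0.00222). Cdca3 (-4.07 ± 0.66), 2810417H13Rik, Uhrf1, Pbk, Dtl, Aurka, Mfap2 and Ccna2 (-3.53 ± 0.78) fell too. There were 295 higher and 449 lower genes (4356 with an unadjusted p below 0.05). Of the lists, 6 of 11 microglia markers rose (11 adjusted over the list alone; median 4.64). So did 2 of 6 infiltrating immune markers (5 higher and 1 lower adjusted over the list alone) and 2 of 10 antigen presentation genes (6 adjusted over the list alone). Calb2 fell (-4.24 ± 0.81; 1 of 12 interneuron markers, 1 adjusted over the list alone), as did 1 of 4 ependymal markers (4 adjusted over the list alone). Aldoc fell among astrocyte markers (-1.95; 9 adjusted over the list alone), with 1 ribosomal protein gene of 81 (0 adjusted over the list alone) and 8 of 92 oxidative phosphorylation genes (27 adjusted over the list alone). Their camera calls were lost with an estimated correlation (adjusted p = 0.409 for the microglia, infiltrating immune, ependymal, astrocyte and oxidative phosphorylation lists, 0.428 for antigen presentation and 0.807 for ribosomal protein genes). Upper-quartile scaling gave 295 higher and 734 lower genes (28.7% against 39.7% higher), and raw totals 248 and 1253 (16.5% higher). The count was 233 without scr2, 99 without scr3, 162 without sh1, 1626 without sh3 and 134 without sh4 (D1neg infected library each). Each of the 10 named genes that rose missed the threshold without 2 or more of the scr1, scr2, scr3, sh1 and sh4 libraries, up to an adjusted p of 0.183 for Pde3b without scr3. Aurka missed it without scr3 (0.0515) or sh4 (0.0514), and Ccna2 without scr3 (0.0574), sh1 (0.0605) or sh4 (0.0653). With whole experiments left out as well, Rrm2, Cdca3, 2810417H13Rik, Uhrf1, Pbk and Dtl also missed it. Their highest adjusted p then ran from 0.0508 (2810417H13Rik) to 0.1 (Pbk), while Cd24a and Mfap2 stayed below 0.05. Trpv4 (3.21 ± 1.11, adjusted p = 0.087) passed without the sh3 library (0.0442; 0.00829 to 0.326 over all alternatives). With voom and the correlation within experiments Mrc1 (0.0636), Pde3b (0.217), Hpgd (0.0683), Hpgds (0.134), Arhgap27 (0.0549), Tbxas1 (0.0647) and Slc11a1 (0.11) missed the threshold and Trpv4 passed it (4.33, adjusted p = 0.041).

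In D1pos infected cells 5 genes passed. Sox18 (4.29 ± 0.71, adjusted p = 0.0254), the iron exporter gene Slc40a1 (3.85 ± 0.70, adjusted p = 0.0475) and the endothelial surface antigen gene Ly6c1 (3.52 ± 0.62, adjusted p = 0.0388) were higher. Slc40a1 was at 4.90 ± 2.19 CPM with the scrambled virus and 70.6 ± 31.2 CPM with shShank3 (uninfected 24 and 36.0), and Ly6c1 at 3.87 ± 1.42 and 44.4 ± 24.4 CPM (uninfected 56.7 and 73.2). The Notch ligand gene Dll4, which was named after its values were seen, was at 0 in the scrambled libraries and at least 106-fold higher, with 5.24 CPM (adjusted p = 0.00309; floor of 3 counts over the group, 0.0495 CPM). Cdkn1a (chromosome 17, 29090976 to 29100727) was at 64.3 ± 17.2 CPM with the scrambled virus and 13.8 ± 3.63 CPM with shShank3, against 16.4 and 20.3 CPM in uninfected cells (-2.22 ± 0.37, adjusted p = 0.0254) and was the only listed gene to pass. Adjusted over the list alone, 8 of 8 oligodendrocyte (median 2.13), 5 of 9 endothelial (2.79), 4 of 11 microglia (2.54), 4 of 6 infiltrating immune (4.15, or 3.81 with a bound) and 2 of 6 OPC markers were higher. In the same way 4 of 12 interferon response genes were lower (-1.20). Those camera calls were lost with an estimated correlation (adjusted p = 0.128, 0.128, 0.443, 0.0524, 0.128 and 0.467). Limma-voom called 0 genes, against 1486 with an unadjusted p below 0.05 in edgeR and 217 adjusted calls in DESeq2. The count was 3, 0 and 3 without scr1, scr2 or scr3 and 1, 10, 3 and 1 without sh1, sh2, sh3 or sh4. Each of the 4 genes named by rule missed the threshold without scr1 (adjusted p = 0.0787), scr2 (0.3 to 0.673), sh1 (0.0599 to 0.169) or sh4 (0.1 to 0.118). Sox18, Slc40a1 and Ly6c1 also did without scr3 (0.128 to 0.228), and Slc40a1 and Cdkn1a without sh3 (0.0842 and 0.106).

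The difference between the viruses was tested for a difference between D1pos and D1neg cells, and no single gene passed. edgeR called 0 genes (1218 with an unadjusted p below 0.05), limma-voom 0 and DESeq2 25. Among the genes with the largest D1pos-minus-D1neg difference, Aldh1a2 was at least 540-fold and Dll4 at least 36.0-fold higher (adjusted p = 0.155). Osr1, at or under the floor in both D1pos groups, is given without a fold. Myh11 was at least 30.5-fold, Lrrc74b at least 27.0-fold, Lum at least 20.1-fold and Slc22a6 at least 6.40-fold higher, with Itih2 at 6.24 ± 2.38 (adjusted p = 0.761). The largest negative differences, all at an adjusted p of 0.761, were in Liph (-7.41 ± 2.14), Psd4 (-6.49 ± 2.23), Lag3, Slco4a1, Itgb5, Pde3b, Cd180 and Piezo1 (-4.53 ± 1.68), of which Lag3 and Cd180 are known from immune cells. No listed gene passed, over all genes or adjusted over the list alone, and the camera calls, such as those on oxidative phosphorylation genes (median 0.54), astrocyte markers (1.44) and interferon response genes (-1.48), were lost with an estimated correlation (adjusted p = 0.641). Without the sh3 D1neg infected library 1 gene passed.

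Uninfected cells, sorted as lacking viral fluorescence, gave the background between the experiments of the viruses. edgeR called 0 genes over both D1 classes (1415 with an unadjusted p below 0.05), limma-voom 0 and DESeq2 105. A block for the experiment number also called genes here, as given with the alternatives. Among the lists, 7 of 8 oligodendrocyte markers were higher with shShank3 adjusted over the list alone (0 over all genes; median 1.85; adjusted p = 0.364 with an estimated correlation). So were 4 of 4 ependymal markers (0 over all genes; median 3.89, or 3.26 with bounds; adjusted p = 0.461 with an estimated correlation) and 2 of 8 heat shock genes (0 over all genes; median 0.66; adjusted p = 0.0756 with an estimated correlation). The ependymal difference rests largely on the sh3 D1neg uninfected library, at a mean marker level of 4.452 log2 CPM against -1.79 to -0.82 in the other 3 shShank3 libraries of its group and -1.66 ± 0.25 in the scrambled ones. Among the largest positive differences were Klk6 (3.73 ± 1.03, adjusted p = 0.394), Cyp2j12 (3.66 ± 0.75, adjusted p = 0.351) and the pacemaker channel gene Hcn2 (3.43 ± 1.05, adjusted p = 0.404). Over all alternatives their lowest adjusted p was 0.014, 1.4e-05 and 0.0209, so that each passed under at least 1 of them. Genes at 0 in a group, whose place in that order is not known, were H2-Aa (at least 9.54-fold), Myo1f (at least 9.15-fold), Fmod (at least 7.26-fold), Rasal3 (at least 5.58-fold) and C5ar2 (at least 3.85-fold). Among the largest negative ones were Col8a1 (at least 3.03-fold lower), Aoc3 (at least 1.54-fold lower), Kcne4, the clock output gene Dbp (-1.42 ± 0.42, adjusted p = 0.394), Prokr2, Xist (-1.31 ± 1.06), Gm42992 and Heyl (-1.19 ± 0.44). Without the sh2 D1neg uninfected library 3 genes passed, without the sh2 D1pos uninfected library 7 (Cyp2j12 among them, adjusted p = 0.0496), and without experiment sh2 107.

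By D1 class the uninfected comparison gave 0 genes in D1pos cells (1094 with an unadjusted p below 0.05; limma-voom 0, DESeq2 41) and 0 in D1neg cells (633; limma-voom 2, DESeq2 17). In D1pos cells the largest positive differences were in Hcn2 (4.98 ± 1.61), Cyp2j12, Dock5, Slain1, Ybx3, Adap1, the myelin gene Mbp (3.51 ± 1.06; 2206 against 25120 CPM) and Prr18. The largest negative ones were in Hif3a, Agt (-1.62 ± 0.55), Igsf1, Gm10800, Heyl, Prkaa2 and Lgr6 (adjusted p of 0.685 to 0.921). In D1neg cells they were in Hapln2 (2.71 ± 0.94), Pdyn, Itgb4, Pde8a, Tac1, Zfpm1, Adap1 and Rhou on the positive side and in Prokr2 (-2.28 ± 1.13), Kcne4, Rassf10, Cd24a (-1.82 ± 0.54), Igfbpl1, Itih2, Atp13a5 and Angptl2 on the negative side (adjusted p = 1 each). In D1pos cells 7 of 8 oligodendrocyte markers (median 2.30; adjusted p = 0.4 with an estimated correlation) and 1 of 8 heat shock genes (0.0788) passed adjusted over the list alone. In D1neg cells 4 of 4 ependymal markers did (median 6.51, or 5.23 with bounds; adjusted p = 0.837 with an estimated correlation), again largely through the sh3 library. Without the sh2 library 1 gene passed in D1neg cells.

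Whether the virus difference depended on the infection gate was tested as an interaction. Dab2, an endocytic adaptor gene of macrophages (chromosome 15, 6299788 to 6440712), was at 165.5 and 194.2 CPM in shShank3 infected D1pos and D1neg cells and at 19.1 to 60.0 CPM in the other 6 groups (3.04 ± 0.47, adjusted p = 0.018). Slc40a1 (3.36 ± 0.62), Rras2 (3.22 ± 0.63), Sox18 (3.14 ± 0.60), Ly6a (2.63 ± 0.54) and Rab11fip5 (1.45 ± 0.26) also had a positive interaction, with adjusted p of 0.0415 to 0.0467. In both D1 classes the scrambled infected cells were below the scrambled uninfected ones for Sox18, Slc40a1 (4.90 and 23.2 against 24 and 242 CPM), Ly6a (5.28 and 51.1 against 43.7 and 300 CPM) and Rras2 (11.4 and 27.4 against 38.5 and 91.9 CPM). With shShank3, infected against uninfected cells held 70.6 and 256 against 36.0 and 245 CPM of Slc40a1, 31.3 and 229 against 44.1 and 206 CPM of Ly6a, and 79.7 and 157 against 40.1 and 40.7 CPM of Rras2. Top2a (-2.90 ± 0.60), the ciliary gene Tmem107 (-2.51 ± 0.51), Hmgb2 (-2.02 ± 0.40) and Dbi (-1.74 ± 0.36) had a negative interaction (adjusted p = 0.0467 each), and for all 4 the scrambled infected cells were above the scrambled uninfected ones in both D1 classes. Ependymal markers had a negative interaction (3 of 4; 4 adjusted over the list alone; median -7.71, or -7.06 with bounds), a list that held with an estimated correlation (adjusted p = 0.0369). Part of it is the difference in uninfected cells (median 3.89), which rests largely on the sh3 D1neg uninfected library (4.452 log2 CPM against -1.79 to -0.82). Of 6 infiltrating immune markers 4 were higher adjusted over the list alone (0 over all genes; median 3.66; adjusted p = 0.0369 with an estimated correlation). Of 9 endothelial markers 5 were higher and of 10 astrocyte markers 1 lower adjusted over the list alone (0 over all genes; adjusted p = 0.419 with an estimated correlation for both, as for microglia markers with a median of 2.62). The camera calls on p53, antigen presentation and oxidative phosphorylation genes and OPC markers (0.419), TRP channel genes (0.284) and ribosomal protein genes (0.592) were lost in the same way. In all, 11 genes had a positive and 15 a negative interaction (1831 with an unadjusted p below 0.05). Outside the rule for named genes, and named after their values were seen, the rest included the ciliary genes Ccdc153 (at least 316-fold), Tmem212 (at least 369-fold), Armc4, Rsph1, Spag16 and Dynlrb2 with a negative interaction.

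With the experiment as a block 49 genes passed (28 positive, 21 negative; 19 of the 26 among them). The calls on Rras2 (adjusted p = 0.064) and Ly6a (2.52, adjusted p = 0.0595) were lost, and 1 of 4 ependymal markers, 1 infiltrating immune marker and 1 astrocyte marker passed. Over all alternatives the adjusted p of Rras2 ran from 9.71e-05 to 0.463 and that of Ly6a from 0.000333 to 0.535. The interaction count moved by over 1.5 times without 25 of the 28 libraries. It was 82 without sh2 D1neg uninfected, 57 without sh3 D1neg infected, 56 without scr1 D1neg infected and 40 without sh1 D1neg uninfected. Fewer genes passed without sh2 D1pos infected (14), sh3 D1neg uninfected (10), sh3 D1pos infected (8), the D1pos uninfected libraries of sh1, sh2 or sh4 (4 each), or scr3 D1neg uninfected, scr3 D1pos infected, sh1 D1neg infected or sh4 D1neg infected (3 each). There were 2 without either uninfected library of scr1 or scr2, without scr3 D1pos uninfected, sh1 D1pos infected, sh3 D1pos uninfected or sh4 D1pos infected, 1 without scr2 D1neg infected, and 0 without scr2 D1pos infected or scr3 D1neg infected. Dab2 was the most stable of the 10 named genes and missed the threshold without scr2 D1pos infected (adjusted p = 0.0727) or scr3 D1neg infected (0.053), while the other 9 missed it without 17 to 24 of the libraries.

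Infected and uninfected cells were compared within each virus. With the scrambled hairpin, ependymal genes rose and endothelial genes fell in infected cells. Foxj1, the master regulator of motile cilia (chromosome 11, 116330704 to 116335399), was at 48.4 and 30.5 CPM in infected D1pos and D1neg cells against 10.7 and 2.26 CPM uninfected (2.97 ± 0.53, adjusted p = 0.00977). All 4 ependymal markers rose (4 adjusted over the list alone; median 6.50, or 5.86 with bounds), Ccdc153 from 2.04 and 0 to 36.6 and 39.1 CPM, and this list held with an estimated correlation (adjusted p = 0.0163). Gfap (1.79 ± 0.36; 1 of 10 astrocyte markers, 8 adjusted over the list alone), Fbxo36, Plagl1, Tmem107, Tppp3, BC034090, Scd1, Fhl1 and Psph (0.97 ± 0.20) rose, as did Cdkn1a among p53 targets (1.32 ± 0.28; 2 adjusted over the list alone). The tight junction gene Cldn5 (-3.02 ± 0.50, adjusted p = 0.0073), the angiopoietin receptor genes Tie1 (-4.00 ± 0.72) and Tek (-3.41 ± 0.64) and Robo4 (-3.80 ± 0.91) fell. So did Pglyrp1 (-3.64 ± 0.46, adjusted p = 0.000643), Sox18 (-3.47 ± 0.49), Cd34, Ctla2a, Adgrl4 and Ly6c1 (-3.09 ± 0.44). Of 9 endothelial markers 4 fell (7 adjusted over the list alone; median -2.61). Astrocyte, p53 and endothelial camera calls were lost with an estimated correlation (adjusted p = 0.139, 0.139 and 0.109). So was that on OPC markers (0 of 6; 3 lower adjusted over the list alone; adjusted p = 0.169) and that on microglia markers (0 of 11, and 0 adjusted over the list alone; median -1.59; adjusted p = 0.528).

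There were 74 higher and 68 lower genes in scrambled infected cells (2097 with an unadjusted p below 0.05). With the experiment as a block there were 258 (113 higher, 145 lower; 127 of the 142 among them), and 5 endothelial markers, 1 OPC marker and 1 interneuron marker were then lower and 1 oxidative phosphorylation gene higher. The count was 59 without scr1 D1neg uninfected, 31 without scr1 D1pos uninfected, 51 without scr2 D1neg infected, 38 without scr2 D1neg uninfected, 47 without scr2 D1pos infected and 79 without scr2 D1pos uninfected. It was 48 without scr3 D1neg infected, 43 without scr3 D1neg uninfected, 43 without scr3 D1pos infected and 40 without scr3 D1pos uninfected. Calls on Plagl1, Tppp3, BC034090, Robo4, Tmem107, Psph, Scd1, Fhl1, Gfap and Fbxo36 were lost without 4 to 11 of these 12 libraries, up to an adjusted p of 0.157 for Robo4 without scr1 D1pos uninfected. Those on Foxj1, Cldn5, Tie1, Tek, Pglyrp1, Sox18, Cd34, Ctla2a, Adgrl4 and Ly6c1 were kept without any 1 of the 12. Without a whole experiment only that on Pglyrp1 was kept each time (adjusted p up to 0.0298), and the other 9 reached 0.0736 (Sox18) to 0.351 (Foxj1).

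With the Shank3 hairpin 5 genes were higher in infected cells and 0 lower (1172 with an unadjusted p below 0.05; limma-voom 30 genes and DESeq2 107). All 5, which fall outside the rule for named genes and were named after their values were seen, are known from border-associated macrophages. Dab2 (2.43 ± 0.32, adjusted p = 0.00122) was at 165.5 and 194.2 CPM infected against 19.1 and 57.7 CPM uninfected in D1pos and D1neg cells. The platelet chemokine gene Pf4 (4.93 ± 0.70, adjusted p = 0.00282) was at 42.8 and 70.1 against 0.420 and 7.90 CPM. Cd163, the haemoglobin scavenger receptor gene (4.81 ± 0.83, adjusted p = 0.0289), Ms4a7 (5.62 ± 0.96, adjusted p = 0.0289) and Cbr2 (4.77 ± 0.85, adjusted p = 0.0322) rose too. Of 6 infiltrating immune markers 2 rose (4 adjusted over the list alone; median 3.63), a list that held with an estimated correlation (adjusted p = 0.0112). Microglia markers (median 0.92; 0 of 11, and 0 adjusted over the list alone), endothelial markers (-0.60) and ribosomal protein genes (-0.26) had camera calls that were lost (adjusted p = 0.815 with an estimated correlation). The infiltrating immune level was 3.42 ± 0.33 and 2.98 ± 1.25 log2 CPM in infected D1pos and D1neg cells against -1.05 ± 1.06 and 1.77 ± 1.12 uninfected. It is a mean over Mrc1, Cd163, Lyz2, Ms4a7, Cd79a and S100a8, and does not show that cells had infiltrated. With the experiment as a block 15 genes passed (11 higher, 4 lower; 5 of the 5 among them) and 3 infiltrating immune markers. The count was 8 without sh3 D1neg infected and 2 without sh1 D1neg uninfected, sh1 D1pos infected, either sh2 uninfected library, sh3 D1neg uninfected, either sh3 D1pos library or any of the 4 sh4 libraries.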

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

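Each shShank3 group of 4 libraries was screened for a single value far from the rest of its group (Dixon's test). The values were the 27 list levels, total counts, genes detected, mitochondrial share, and Shank3, Trpv4, Drd1 and Drd2. Of 136 such tests about 1 in 20, or 6.8, are flagged by chance, and 4 stood out. The scrambled groups of 3 were not screened. The mean OPC marker level of the sh2 D1pos uninfected library was 6.32 log2 CPM against 7.74 to 7.98 in the other 3. The endothelial and mural level of the sh3 D1neg infected library was 5.315 against 7.59 to 7.83. In the sh3 D1neg uninfected library the ependymal and choroid level was 4.452 against -1.79 to -0.82, and the antigen presentation level 4.578 against 6.39 to 6.57. Fewer groups stood out than chance would give. The ependymal level is given beside the results it carries, and the others are not read further.

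The interaction was singled out because the same comparison of viruses came out differently in infected and uninfected cells by a direct test, in 26 genes. The named ones, as log2 differences between the gates, were Slc40a1 (3.36), Rras2 (3.22), Sox18 (3.14), Dab2 (3.04), Ly6a (2.63), Rab11fip5 (1.45), Top2a (-2.90), Tmem107 (-2.51), Hmgb2 (-2.02) and Dbi (-1.74).

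For the rise of macrophage genes in infected cells, both tests were written down before they were run. If the shShank3 infected fractions held more immune RNA, called genes would follow the microglia marker level in uninfected libraries. Over the 14 uninfected libraries, with the mean of each group taken off, the median correlation with that level was 0.59 for genes called higher and -0.27 for genes called lower, against -0.02 for uncalled genes, and genes called higher lay 0.61 above uncalled ones (0.55 to 0.66 with each experiment left out). More immune RNA in these fractions than in the scrambled infected ones may thus explain part of this comparison. If the difference had been present before the infection gate, it would be seen in uninfected cells, but the median shift there was 0.15 of that in infected cells (0.28 against 1.90; 0.09 to 0.20 with each experiment left out). A difference of the whole tissue is thus unlikely to be the whole cause. It could be part of it, since 1103 of the 1448 genes (76.2%) had the same sign in uninfected cells, and genes chosen for a large infected difference lower the ratio. The viruses differ in serotype and fluorophore as well as in hairpin, and macrophage uptake or autofluorescence could place such cells in the infected gate; the ratio of 0.15 does not separate this from an effect of the hairpin.

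For the rise of Trpv4, the tests were chosen after the result was seen. With the infiltrating immune marker level as a covariate the Trpv4 difference was 1.73 ± 1.43 (adjusted p = 0.649) instead of 3.19 ± 0.79, and with the microglia level 1.41 ± 0.84 (adjusted p = 0.415). Trpv4 is expressed by macrophages as well as by neurons and glia, so the rise may come with the macrophage content, but the error of 1.43 leaves both readings open. Endothelial and mural markers were also higher in infected cells with shShank3. Their level was 4.56 (D1pos) and 7.11 log2 CPM (D1neg), against 2.29 and 6.29 with the scrambled virus. It was not tried as a covariate, so a part of the vascular content in the rise was not tested.

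For the lower Shank3 in shShank3 infected than uninfected fractions, the test was chosen after the result was seen. Shank3 fell less clearly once the MSN content was taken off: the difference was -1.06 for Shank3 and -0.61 for the pan-MSN level, leaving -0.45 (SE 0.19). This was lower in 4 of 4 experiments and in 6 of 8 pairs, with sh2 D1pos (0.34) and sh3 D1pos (0.37) the other way, and had an exact two-sided sign-flip permutation p of 0.125, the smallest possible with 4. A knockdown within neurons and a smaller share of neurons in the infected gate could each give this, and -0.45 does not tell them apart. The scrambled pairs were not treated in this way, so -0.45 is not shown to be particular to the shShank3 virus. In scr1 to scr3 Shank3 itself differed by 0.57, -1.02 and -1.12 (D1pos) and by 0.18, 0.43 and -0.52 (D1neg).

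Regrouping of samples was used to ask whether chance can be excluded. With whole experiments regrouped, no other grouping reached the real count for the mean of infected cells (1448 against 1164 at most, 1 of 35) or for the interaction (26 against 3, 1 of 35). This share of 0.0286 is the smallest possible, and it speaks against chance only if experiments are free to regroup. Equal numbers were alike (mean r of 0.13 to 0.205, against -0.16 to 0.041 for other numbers), so that condition is in doubt. If equal numbers share a day or batch, only the 8 ways within numbers count, too few for a share under 0.05 (1448 against 0 and 26 against 0). With fractions swapped within pairs, no other way reached it for D1pos against D1neg (6256 against 2032, 1 of 30), for infection with the scrambled virus (142 against 8, 1 of 32) or with shShank3 (5 against 3, 1 of 40). Fractions of an experiment correlate, so all fractions of an experiment were then swapped together, a test chosen after the results were seen. For D1pos against D1neg no other way reached 6256 genes (highest 5339, with sh3 swapped, 1 of 64). This speaks against chance only if experiments are independent, which the likeness of equal numbers leaves in doubt here too. For infection the ways are too few for a share under 0.05, with the scrambled virus (142 against 0, 4 ways) and with shShank3 (5 against 0, 8 ways). Chance cannot be excluded for D1pos infected (5 against 6, 2 of 35) or D1neg infected cells (744 against 1518, 3 of 35). Within equal numbers no other way reached these counts (5 against 0 and 744 against 1), but 8 ways are too few for a share under 0.05. For the comparisons with 0 genes regrouping cannot decide, since every grouping calls at least 0 (35 of 35 each). These were the mean of uninfected cells (highest other 544), uninfected D1pos (150), uninfected D1neg (11) and the D1pos-minus-D1neg difference (2). The groupings with most genes set sh1, sh2 and sh4 against the rest in infected cells (1164 and 1518), that is, sh3 with the scrambled experiments. They set sh1, sh3 and sh4 against sh2 with the scrambled ones in uninfected cells (544). This points to a structure of the samples in which sh3 and sh2 differ from the other shShank3 experiments.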

How the results depend on the processing

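The viruses differ in serotype and fluorophore beside the hairpin, the experiments are few, and fractions of an experiment are not independent, so the p-values of the virus comparisons take 14 infected libraries of 7 experiments as separate. Where a result moved under an alternative, the cause was not tested unless stated. The correlated voom model, the block for the experiment, the summed D1 fractions and the removal of whole experiments were chosen after seeing the data. The other alternatives were chosen before.

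DESeq2 called more genes than edgeR in every comparison: 2827 for the mean of infected cells (1629 higher, 1198 lower), 105 for the mean of uninfected cells (97 higher, 8 lower), and 393 for the interaction. It called 217 for D1pos infected, 2602 for D1neg infected, 41 for D1pos uninfected and 17 for D1neg uninfected cells, 25 for the D1pos-minus-D1neg difference, and 632 and 107 for infection with the scrambled and the shShank3 virus. On simulated data it also called more unchanged genes than edgeR. Under DESeq2 the Trpv4 interaction passed (3.81, adjusted p = 0.00425). Limma-voom called 4 genes for the interaction, 0 for D1pos infected, 2 for D1neg uninfected cells, and 244 and 30 for infection with the scrambled and the shShank3 virus. Without the expression filter 17 genes passed for the interaction, 10 for D1pos infected cells, 455 for D1neg infected cells and 3 for infection with shShank3, and with the strict filter 10 passed for D1pos infected cells.

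Fractions of the same experiment were alike (mean r of 0.135 to 0.407). Equal numbers across the viruses were also alike (mean r of 0.13 to 0.205, with 0.027 for the lowest fraction pair), other numbers less so (-0.16 to 0.041), and 22 of 24 libraries correlated best with their own number. A shared factor behind the numbers is thus open, but the labels do not tie them, so the viruses were not paired. A block for the number gave 20 genes for the mean of uninfected cells (18 higher, 2 lower), 9 for D1pos infected and 1384 for D1neg infected cells, in which Trpv4 then passed (3.42, adjusted p = 0.0474). A block for the experiment gave 49 genes for the interaction, 258 for infection with the scrambled virus and 15 with shShank3, and beside the changes given with the results it changed no other call on a named gene. The voom model with the correlation within experiments gave 442 genes for the mean of infected cells (168 higher, 274 lower), 149 for the interaction, 0 for D1pos infected cells, 1 for D1neg uninfected cells, and 514 and 50 for infection with the scrambled and the shShank3 virus. Under it the Trpv4 interaction passed (4.28, adjusted p = 0.0369).

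Summing reduces the number of libraries, which lowers what can pass. Summing the D1 fractions also no longer takes correlated fractions of an experiment and gate as separate libraries. The calls lost in that way therefore cannot be put down to fewer libraries alone. With counts summed per group 42 genes passed for the mean of infected cells, 0 for the interaction, and 15 and 0 for infection with the scrambled and the shShank3 virus, and with D1 class by virus added 0 passed in each of these 4. With the D1 fractions summed 95 (31 higher, 64 lower) passed for the mean of infected cells, 0 for the interaction, and 0 and 0 for infection. The per-sample tables, without sh4, gave 190 genes for the mean of infected cells, 1 for the interaction, 1 for D1pos infected and 32 for D1neg infected cells, and 44 and 0 for infection. With only the groups compared in the fit 0 genes passed for D1pos infected and 0 for D1neg infected cells. The Trpv4 difference in infected cells was 3.32 (adjusted p = 0.0824) with summed counts, 3.26 (0.107) with D1 class by virus added, 3.20 (0.063) in the per-sample tables and 3.18 (0.0598) with summed fractions. Of the 93 camera calls on lists 4 remained with an estimated correlation, and 34 lists passed with fry.

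The sign of some uncalled genes changed. In the mean of uninfected cells Shank3 was at -0.10 with voom and -0.11 with correlated voom, Drd2 at -0.54, -0.58 and, with the number block, -0.34. Fmod was at -1.11 with summed fractions, and Aoc3 at 0.24 with summed counts, 0.72 with D1 class by virus and 0.25 with summed fractions. In the interaction Drd1 was at -0.25 with voom, -0.24 with correlated voom, -0.01 with summed counts, -0.15 with D1 class by virus and -0.08 with summed fractions. In D1pos infected cells Shank3 was at 0.06 in the per-sample tables, and Drd2 at -0.28 with the number block and -0.04 with correlated voom. In D1pos uninfected cells Trpv4 was at -0.04 with RLE, -0.03 with upper quartiles, -0.15 with raw totals, -0.04 with DESeq2, -0.04 without a filter and -0.09 with the strict one. Drd2 was at -0.24 with voom, -0.19 with the number block and -0.36 with correlated voom. In D1neg uninfected cells Drd2 was at -0.84, -0.49 and -0.80 with these 3. For the D1pos-minus-D1neg difference Shank3 was at -0.05 with RLE, -0.05 with DESeq2, -0.12 with the strict filter and -0.08 with only the groups compared. Trpv4 was at 0.11 with upper quartiles, 0.16 with raw totals, 0.06 without a filter and 0.11 with the number block.

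Leaving out a library or an experiment moved the mean of infected cells from 75 (without experiment scr3) to 2790 genes (without sh3), with 175 without scr2, 346 without sh1 and 190 without sh4. There Shank3 ran from -1.34 to 0.05, Trpv4 from 2.74 to 3.80, Drd1 from -0.24 to 1.51 and Drd2 from -0.92 to 0.43. In the mean of uninfected cells 0 to 107 genes passed (107 without sh2), with Shank3 at -0.28 to 0.77, Trpv4 at -0.94 to 0.25, Drd2 at -0.05 to 1.48 and Aoc3 at -3.31 to 0.00. In the interaction 0 to 82 passed (7 without experiment scr1, 0 without scr2, scr3 or sh1, 17 without sh3, 1 without sh4), with Drd1 at -0.86 to 0.79. In D1pos infected cells 0 to 14 passed (0 without experiment scr2, 1 without scr3, sh1 or sh4, 14 without sh2, 8 without sh3), with Shank3 at -1.07 to 0.08, Drd1 at -0.91 to 0.46 and Drd2 at -0.28 to 0.88. In D1neg infected cells 19 to 2660 passed (416 without experiment scr1, 101 without scr2, 19 without scr3, 90 without sh1, 2660 without sh3, 32 without sh4), with Shank3 at -1.68 to 0.16. In D1pos uninfected cells Shank3 was at -0.51 to 0.58, Trpv4 at -0.61 to 1.40 and Drd1 at -0.68 to 0.50. In D1neg uninfected cells 0 to 1 genes passed, with Shank3 at -0.08 to 1.20 and Drd2 at -0.27 to 1.43. For the D1pos-minus-D1neg difference 0 to 1 passed (1 without sh2), with Shank3 at -0.79 to 1.48 and Trpv4 at -0.69 to 0.61. Infection with the scrambled virus gave 1 to 199 genes (40 without experiment scr1, 1 without scr2, 8 without scr3), with Drd1 at -1.01 to 0.25 and Drd2 at -0.24 to 0.48. With shShank3 it gave 0 to 8 (2 without experiment sh1, 1 without sh2 or sh3, 0 without sh4), with Drd1 at -1.30 to 0.35.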

Other observations

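Genes of dividing cells and of young neurons were looked at after the results had been seen, and both lists and all their tests were chosen then. Genes of the cell cycle had by then been seen to fall in these same libraries. The adjusted p-values of the cell cycle list therefore cannot decide whether such genes fall as a set, and are given as a description. They were also adjusted over this list and the neuroblast list only. They are thus not comparable with those of the lists written before the counts were seen. Cell cycle genes from a published list (95 of 97 measured) were at 5.11 ± 0.63 log2 CPM in scrambled D1neg infected cells (n = 3) and at 2.51 ± 0.87 in the shShank3 ones (n = 4). In infected cells Hmgb2 (-2.20 ± 0.28, adjusted p = 0.000496), Birc5 (-2.86 ± 0.43) and the replication helicase gene Mcm7 (-1.59 ± 0.28) fell, with Hmgb2 at 244 CPM in scrambled D1neg infected cells against 25.9 with shShank3. Over the mean of infected cells the median of the list was -1.78, with 59 genes lower (74 adjusted over the list alone; adjusted p = 0.0136 with an estimated correlation). In D1neg infected cells 50 fell (76 adjusted over the list alone; median -2.58; adjusted p = 0.00449 with an estimated correlation), and in D1pos infected cells 0 (median -0.94; adjusted p = 0.132). The direct test of D1pos against D1neg gave a median of 1.44 (0 genes over all, 3 adjusted over the list alone; adjusted p = 0.03 with an estimated correlation). In uninfected cells the median was -0.08 (adjusted p = 0.533; D1neg -0.61, adjusted p = 0.0632; D1pos 0.43, adjusted p = 0.404), and the interaction was -1.73 (2 lower, 46 adjusted over the list alone; adjusted p = 0.0166 with an estimated correlation). From uninfected to infected cells the median was 0.60 with the scrambled virus (adjusted p = 0.306) and -1.09 with shShank3 (0 of 95; 42 adjusted over the list alone; adjusted p = 0.00752). The cell content of these fractions also differed. In D1neg infected cells the microglia marker level was 9.47 ± 2.94 log2 CPM with shShank3 against 5.37 ± 1.59 with the scrambled virus, though only 5.26 in sh3. What makes the cell cycle genes differ was not tested.

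The neuroblast list of 10 genes was written after its members had been seen to fall, so its levels are given without a test. Its median in the mean of infected cells was -1.55. In D1neg cells it was at 6.13 ± 0.80 (infected) and 6.83 ± 0.56 log2 CPM (uninfected) in the scrambled experiments, against 3.43 ± 0.38 and 5.10 ± 1.20 with shShank3. In D1pos cells it was at 3.01 ± 0.62 and 3.71 ± 0.24 against 2.61 ± 0.65 and 4.10 ± 0.16, so that uninfected D1pos cells held more with shShank3. Single members called in infected cells were Cd24a (-2.53 ± 0.39, adjusted p = 0.00102), Ccnd2 (-1.83 ± 0.31), Sox11 (-1.56 ± 0.33), Dlx1 (-1.83 ± 0.43) and Tubb3 (-1.52 ± 0.43), whereas Dlx2 did not pass (-1.24 ± 0.39, adjusted p = 0.0517). In D1neg infected cells Ccnd2 went from 763.7 to 114 CPM and Sox11 from 223 to 35.9 CPM.

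Xist, expressed from the inactive X chromosome of female cells, was at 0, 0, 0.609 and 0.0992 CPM in the 4 sh4 libraries and at 29.6 to 318 CPM in the other experiments, while the Y-linked genes Ddx3y and Eif2s3y were present in all libraries. This fits tissue from males only in sh4 and from both sexes in the other experiments. Sex is thus not balanced over the experiments. Levels also differed between fractions of 1 experiment. Ddx3y ran from 1.83 (D1neg infected) to 29.2 CPM (D1pos uninfected) in sh1 and from 12.3 to 71.7 CPM in the same fractions of sh3. In sh2 it ran only from 60.5 to 84.0 CPM. Xist ran from 87.5 (D1pos uninfected) to 298 CPM (D1neg infected) in sh3. Fractions of an experiment are thus not shown to be matched for sex.

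In the sh3 D1neg libraries Drd1 was higher than in the sh3 D1pos libraries, at 415 and 313 against 102 and 142 CPM, the opposite of the sort. Drd2 ran as labelled there, at 62.7 and 106.7 CPM in the D1neg against 10.3 and 26.6 CPM in the D1pos libraries. The sh3 D1neg libraries also had the highest mitochondrial shares, and Shank3 was at its highest in them. Their pan-MSN marker levels were the highest of all libraries too, at 8.26 (infected) and 8.28 log2 CPM (uninfected). The sh3 D1pos libraries held 6.11 and 6.77 log2 CPM. A larger share of neuron RNA in the sh3 D1neg libraries is thus not separated from their Drd1 and Shank3 levels.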
